A study of Sordaria macrospora with 5 samples.

How the data were processed

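The series measured gene expression by paired-end RNA sequencing in Sordaria macrospora, a filamentous ascomycete that forms fruiting bodies (perithecia) from young precursors called protoperithecia. The 5 libraries fell into 3 groups by the strain and tissue in the labels: wild-type mycelium (1 library), nox1 mycelium (2 libraries) and nox1 protoperithecia (2 libraries). The nox1 strain lacks the gene for an NADPH oxidase, an enzyme that makes superoxide. The series' design text calls the paired nox1 libraries independent biological replicates. Per the labels, mycelium was taken during sexual development and gave total RNA, while protoperithecia were microdissected and their RNA was amplified, so tissue and amplification cannot be separated in any comparison between them.

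The authors deposited 1 table of 10091 locus tags with a whole-number read count per gene and library, not normalised, per the file headers. The aligner, the counting tool, its use of strand, the genome build and the annotation are not given in the sources used here, so reads shared by near-identical or overlapping genes could not be told apart. The same table holds the authors' score for 8 comparisons, a consensus call of 1 (higher), -1 (lower) or 0 per gene. Per the file headers, a call required a ratio above 4 or below 0.25 (above 8 or below 0.125 between total and amplified RNA) by both DESeq and an analysis termed classic, a DESeq adjusted p of at most 0.1 and a classic group of 1 to 4. The authors' ratio per gene and comparison is a linear ratio of DESeq-normalised means, per the file headers. DESeq is also the tool named in the submitters' processing notes, without a version. Wild-type and pro1 protoperithecia enter the authors' comparisons through libraries of an earlier study, per the file headers. The 4 per-library count columns of that study were not used here. Per the labels, the strains of the present series were grown on cornmeal medium in place of the medium of that earlier study, so the authors' ratios of nox1 to wild-type protoperithecia and of wild-type protoperithecia to mycelium cross studies and media.

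Library totals ranged from 31000371 to 53786457 counts. A count of 0 allows up to 3 counts, which is 0.0716 CPM (counts scaled to a common library total) in the wild-type library, 0.0635 and 0.0539 in nox1 mycelium replicates 1 and 2, and 0.0783 and 0.076 in nox1 protoperithecia replicates 1 and 2. Such floors cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per gene with 10 or more summed counts was 239 for the protoperithecia replicates, the closest pair.

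Differential expression was tested with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; robust glmQLFit and glmQLFTest, two-sided) on the deposited counts. Factors were trimmed means of M-values (TMM), and the edgeR default filter by expression removed 173 genes and left 9918. All 5 libraries and 3 groups entered a single fit with group as the only term and 2 residual degrees of freedom. The common biological coefficient of variation was 0.59, and genes shared information on the spread with a median of 6.9 prior degrees of freedom. A gene was called at an adjusted p (Benjamini-Hochberg) below 0.05 with no fold minimum. Standard errors (SE) of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values and floors carry the TMM factors. RPKM values were computed from the counts, the plain library totals and the gene length. The wild type has 1 library, so its spread was assumed to be that of the nox1 groups.

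The samples, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The named-gene rule took, per comparison, the 2 highest and the 2 lowest log2 fold changes among called genes with a mean of 20 or more counts in the higher group and no overlap between the libraries of the groups, since no table used here pairs these locus tags with gene names. The RefSeq gene table of assembly ASM3387043v1 matched 9585 locus tags (95%) and gave 0 gene symbols. None of the 29 gene lists drawn up for the study matched a gene (0 lists), so their set tests and the level of the nox1 transcript are not reported here. The table served only for gene length and for which genes neighbour each other.

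Overlaps between the calls made here and the authors' deposited calls were added after the table was seen. They were restricted to authors' comparisons that share no library with the comparison made here, and were tested with two-sided Fisher's exact tests over the 9918 genes. Shares have exact Clopper-Pearson 95% intervals. The tests and intervals treat genes as independent and the calls as fixed, so they do not measure variation between cultures or libraries. Since abundant genes are called more readily, 10000 random gene lists matched on mean expression in 20 bins were drawn for each overlap.

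The fit was tested on simulated data with 200 changed genes, all other genes unchanged and the spread taken from its trend with expression. The shares recovered hold for that setting. For protoperithecia against mycelium (9894 genes), 26% of changes of log2 size 2 and 80% of those of log2 size 4 were recovered, with 5 false calls among 111. For nox1 against wild-type mycelium (9892 genes), the shares were 15% and 75%, with 4 false calls among 94. Alternatives were RLE and upper-quartile factors, no low-count filter, a filter of CPM above 5 in 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), only the groups compared, a 2-fold minimum (glmTreat), a replicate block and each nox1 replicate left out in turn. Plain library totals were added after seeing the data.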

Results

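Transcript levels were compared in mycelium of wild-type Sordaria macrospora (1 library), mycelium of the nox1 deletion strain (2 libraries) and microdissected protoperithecia of the nox1 strain (2 libraries). Total counts were 38076151 for wild-type mycelium, 31000371 and 53786457 for nox1 mycelium replicates 1 and 2, and 52731732 and 49727755 for nox1 protoperithecia replicates 1 and 2. Between 8806 and 9913 of the 10091 genes had 10 or more counts in each library. The protoperithecia replicates correlated at r = 0.974 in log2 CPM across genes, and the nox1 mycelium replicates at r = 0.845. The SD of the log2 difference between replicates was 0.871 and 1.71. The wild-type library correlated at r = 0.816 (SD 1.57) with nox1 mycelium replicate 1 and at r = 0.875 (SD 1.47) with replicate 2. The chi-square per gene was 1170 between the nox1 mycelium replicates, and 1260 and 1690 between the wild type and replicates 1 and 2, so the measures ranked these pairs differently. Nox1 mycelium replicate 1 differed from the other libraries at the low end of expression. Its 5th percentile over genes was 3.44 RPKM (reads scaled by gene length and library total), against 0.58 in the wild type, 0.204 in nox1 mycelium replicate 2 and 0.0119 and 0.00811 in the protoperithecia.

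The comparison of nox1 with wild-type mycelium asked which transcripts depend on the NADPH oxidase during sexual development. Nox1 mycelium showed reduced levels of 109 genes and raised levels of 9. The reduced genes had a median of 257 CPM in the wild-type library and of 10.6 and 8.39 CPM in the nox1 mycelium replicates, and their median log2 fold change was -4.48 (quartiles of size 3.76 and 5.41, median SE 0.61). In nox1 protoperithecia, which entered the fit only through the shared scaling, filter and spread, their medians were 13.3 and 10.8 CPM. The raised genes had a median of 9.43 CPM in the wild type and of 120 and 152 CPM in nox1 mycelium, with a median log2 fold change of 4.02 (quartiles 3.74 and 4.60, median SE 0.71). Their medians in nox1 protoperithecia were 17.7 and 22.7 CPM.

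SMAC_09010 had 2490 CPM in wild-type mycelium against 3.98 and 1.65 CPM in the nox1 mycelium replicates. The log2 fold change was -9.79 (SE 1.08, edgeR adjusted p = 0.00459). SMAC_00127 fell from 1280 CPM to 1.93 and 1.42 CPM, a log2 fold change of -9.58 (SE 0.67, edgeR adjusted p = 0.00143). In the nox1 protoperithecia libraries the genes had 11 and 1 counts and 4 and 7 counts, respectively. Wild-type protoperithecia were called lower than wild-type mycelium by the authors for both genes, with ratios of 0.0201 and 0.00968. These ratios divide by the same wild-type mycelium library whose high values helped select the genes, so they are not separate evidence. They also cross studies, media and RNA amplification. The authors' ratios of nox1 to wild-type protoperithecia were 0.0029 and 0.0104, both called lower. The authors' deposited table gives a pro1 to wild-type ratio in protoperithecia of 0.00506 for SMAC_09010 and of 0.0246 for SMAC_00127, both called lower there.

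In the opposite direction, SMAC_02514 had 8 counts in wild-type mycelium and 11170 and 13553 counts in the nox1 mycelium replicates, a log2 fold change of 10.27 (SE 0.96, edgeR adjusted p = 0.00198). In the nox1 protoperithecia it had 370 and 665 counts. SMAC_09757 had 6.02 CPM in wild-type mycelium and 108 and 236 CPM in nox1 mycelium, a log2 fold change of 4.84 (SE 0.80, edgeR adjusted p = 0.0264). Its level in nox1 protoperithecia was 17.7 and 22.7 CPM. With limma-voom the adjusted p was 0.129 for SMAC_02514 and 0.104 for SMAC_09757.

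Nox1 mycelium replicate 1 exceeded replicate 2 by 4-fold or more in 4 (3.67%) of the lower genes, 0 of the higher genes and 1621 (16.5%) of the genes not called. A gap between these replicates widens the spread and works against a call. The shares are thus partly set by the calling and decide nothing about replicate 1. At an unadjusted p below 0.05 in the edgeR test, 602 genes were lower and 289 higher. The authors' deposited table calls 240 genes lower and 16 higher for the same libraries, and 108 of the 109 lower and 7 of the 9 higher genes are among them, with 0 called in the opposite direction. The number of called genes and their split moved with the setting. The 118 genes (92.4% lower) became 445 with DESeq2 (319 lower, 126 higher) and 47 with limma-voom (47 lower, 0 higher). They became 1344 without nox1 mycelium replicate 1 (747 lower, 597 higher, 55.6% lower) and 1277 without nox1 mycelium replicate 2 (774 lower, 503 higher, 60.6% lower), where the spread came from the protoperithecia replicates alone. With 1 wild-type library, its own replicate error was not measured.

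**Figure D1:**
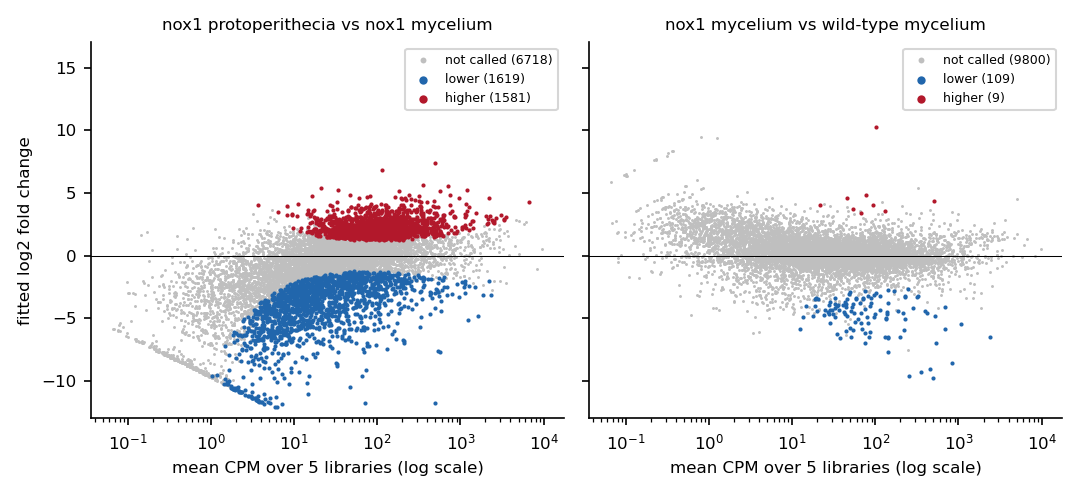
Fitted log2 fold change of each gene (vertical axis) against mean CPM over the 5 libraries (horizontal axis, log scale) for nox1 protoperithecia against nox1 mycelium (left) and nox1 against wild-type mycelium (right), with called genes in blue (lower) and red (higher) and other genes in grey. The left panel has 1619 lower and 1581 higher genes, and the right panel 109 lower and 9 higher genes.

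The genes reduced in nox1 mycelium were next compared with the authors' calls for protoperithecia of nox1 and of a further sterile mutant, pro1, against those of the wild type. Of the 109 genes, 72 (66.1%, 95% interval 56.4 to 74.9) are called lower in nox1 than in wild-type protoperithecia in the authors' deposited table, against 5.87% of all genes tested (6.4 genes expected, ratio 11.3, Fisher's exact p = 6.97e-63). For pro1, which lacks a transcription factor needed for fruiting body development, 67 of the 109 genes (61.5%, 95% interval 51.7 to 70.6) are called lower than in wild-type protoperithecia in the authors' deposited table, against 7.42% of all genes (8.09 expected, ratio 8.28, Fisher's exact p = 1.8e-48). Without nox1 mycelium replicate 1 or 2 the ratio was 5.73 and 3.61 for nox1 and 4.61 and 3.26 for pro1. The calls in the opposite direction were 0 and 4. Neither of those comparisons shares a library with the mycelium comparison, and the pro1 comparison lies within the earlier study. Both use the same wild-type protoperithecia libraries, so the overlaps are not independent of each other. The p-values and intervals treat genes as independent draws and do not cover the error of the single wild-type mycelium library. Among 10000 random lists matched on expression, the highest overlap was 16 genes for nox1 and 20 for pro1. The matching used the mean log2 CPM over the 5 libraries, not the wild-type level (median 257 CPM in the 109 genes). An effect of wild-type abundance on the overlaps was therefore not fully removed. Across genes, which are not independent replicates, the mycelium log2 fold changes correlated with the log2 ratios in the authors' deposited table at r = 0.421 (rho 0.33, 9337 genes) for nox1 protoperithecia and r = 0.431 (rho 0.358, 9334 genes) for pro1 protoperithecia.

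**Figure D2:**
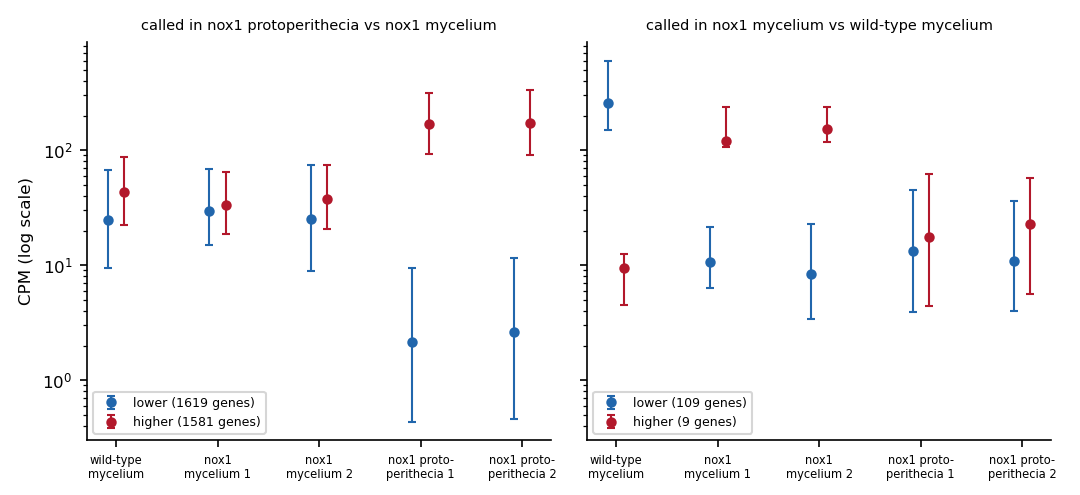
Median CPM with quartiles (vertical axis, log scale) in each of the 5 libraries (horizontal axis) of the genes called lower (blue) and higher (red) in each comparison. The 109 genes lower in nox1 mycelium have a median of 257 CPM in the wild type and of 8.39 to 13.3 CPM in the nox1 libraries.

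The comparison of nox1 protoperithecia with nox1 mycelium asked how the young fruiting bodies of the mutant differ from the whole sexual mycelium. Protoperithecia had lower levels of 1619 genes and higher levels of 1581. The lower genes went from medians of 29.4 and 25.4 CPM in the mycelium replicates to 2.14 and 2.61 CPM in the protoperithecia, a median log2 fold change of -3.60 (quartiles of size 2.47 and 5.22, median SE 0.69). The higher genes went from 33.6 and 37.8 CPM to 169 and 173 CPM, a median log2 fold change of 2.14 (quartiles 1.76 and 2.64, median SE 0.48). Changes of 8-fold or more were 994 decreases and 234 increases. These became 1763 and 372 without nox1 mycelium replicate 2, 490 and 195 without protoperithecia replicate 1, and 563 and 226 without protoperithecia replicate 2. They were 1288 and 75 with upper-quartile factors, 1239 and 67 with plain library totals, 1544 and 236 with DESeq2 and 457 and 247 with limma-voom. In wild-type mycelium the lower genes had a median of 24.5 CPM and the higher genes of 43.1 CPM.

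SMAC_05683 had 1053 and 142 counts in the nox1 mycelium replicates and 0 counts in both protoperithecia libraries, at least 159-fold lower than the mycelium mean against a floor of 3 counts per library and at least 33-fold lower than mycelium replicate 2 alone (edgeR adjusted p = 0.0063). SMAC_05292 had 1120 and 27 counts in mycelium and 0 in both protoperithecia libraries, at least 155-fold lower by the same measure and at least 6.2-fold lower than mycelium replicate 2 alone (edgeR adjusted p = 0.0141). With limma-voom the adjusted p was 0.137 for SMAC_05683 and 0.267 for SMAC_05292. In all, 71 of the lower genes had 0 counts in both protoperithecia libraries, and with these at their bound the median log2 fold change stayed at -3.60. SMAC_06380 rose from 2.22 and 2.39 CPM to 300 and 214 CPM, a log2 fold change of 6.80 (SE 0.55, edgeR adjusted p = 0.00148), and had 47.3 CPM in wild-type mycelium. The authors' ratio of wild-type protoperithecia to mycelium was 1.9 for SMAC_06380 and 1.71 for SMAC_03842, neither called. For SMAC_05683 and SMAC_05292 it was 0.038 and 0.0183, both called lower. SMAC_03842 had 32.1 and 2.95 CPM in mycelium and 273 and 1470 CPM in protoperithecia, a log2 fold change of 5.64 (SE 1.25, edgeR adjusted p = 0.0107). Without nox1 mycelium replicate 1 the log2 fold change was 8.21 (edgeR adjusted p = 0.262), and without replicate 2 it was 4.71 (edgeR adjusted p = 0.155). Without protoperithecia replicate 1 or 2 it was 6.33 and 3.97, with the call kept.

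The authors' deposited table calls 1638 genes lower and 90 higher for this comparison, which includes 1033 of the lower and 88 of the higher genes found here, with 0 in the opposite direction. The shares that follow are partly set by the calling, since a gap between the nox1 mycelium replicates widens the spread. Nox1 mycelium replicate 1 exceeded replicate 2 by 4-fold or more in 246 (15.2%) of the lower genes, 14 (0.886%) of the higher genes and 1365 (20.3%) of the genes not called. Without that replicate 4987 genes were called, 2400 lower and 2587 higher, and 3003 of the original 3200 were kept. The split depended on scaling. Lower genes made up 50.6% of calls with TMM factors, 73.4% with upper-quartile factors (2193 lower, 795 higher) and 75.1% with plain library totals (2066 lower, 685 higher), which moved the median log2 fold change of all genes by -0.67 and -0.74. Fold changes also followed gene length: the log2 fold change correlated with length across genes at rho = 0.237 (9575 genes; -0.0422 in the mycelium comparison), and its median was -1.46 in genes up to the 25th percentile of length (343 lower, 169 higher) and 0.25 in those above the 75th (434 lower, 579 higher). A limma-voom fit called 794 lower and 1391 higher. Without nox1 mycelium replicate 2 there were 5906 calls, and without protoperithecia replicate 1 or 2 there were 833 and 966.

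These genes were compared with the authors' calls for wild-type protoperithecia against wild-type mycelium, which share no library with the nox1 comparison. That contrast also sets amplified against total RNA, and it crosses studies and media, since the wild-type protoperithecia come from the earlier study. Of the 1619 lower genes, 833 (51.5%, 95% interval 49 to 53.9) are called lower in wild-type protoperithecia than in wild-type mycelium in the authors' deposited table, against 12.1% of all genes (196 expected, ratio 4.25, a Fisher's exact p too small to be represented), and 0 are called higher. Of the 1581 higher genes, 49 (3.1%, 95% interval 2.3 to 4.08) are among the 76 genes called higher in the authors' deposited table, against 0.766% of all genes (12.1 expected, ratio 4.04, Fisher's exact p = 1.47e-21), and 1 is called lower. The ratio for lower genes was 3.05 and 2.74 without nox1 mycelium replicate 1 or 2 and 6.42 and 6.32 without protoperithecia replicate 1 or 2. For higher genes it was 2.83 and 2.01, and 9.89 and 12. The highest overlaps among 10000 matched random lists were 334 and 30 genes. The log2 fold changes in nox1 and the log2 ratios in the authors' deposited table for the wild type correlated across genes at r = 0.678 (rho 0.707, 9472 genes). By direction alone, 1466 of the 1581 higher genes had an authors' ratio above 1 and 115 below 1 (median 3.35). Of the 1619 lower genes, 1518 had an authors' ratio below 1 and 101 above 1 (median 0.0933). The shares of all tested genes above and below 1 were not computed, so these counts have no baseline.

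**Figure D3:**
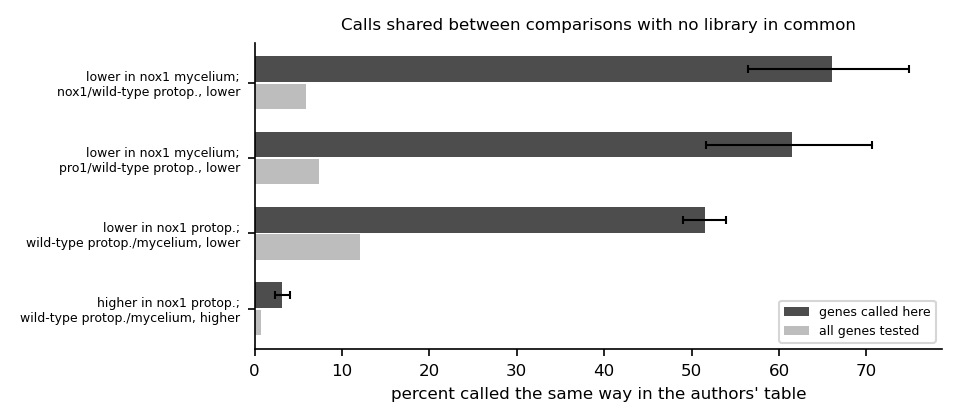
Percent of the genes called here (dark bars, exact 95% intervals) and of all genes tested (light bars) that the authors' deposited table calls in the same direction (horizontal axis) in a comparison with no library in common, for each of 4 overlaps (vertical axis). The shares are 66.1%, 61.5%, 51.5% and 3.1% for the called genes against 5.87%, 7.42%, 12.1% and 0.766% of all genes. The authors' calls required a minimum fold, and the calls made here did not.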

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

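Plain library totals were chosen after seeing the data, and the other settings were planned. The 118 genes changed between nox1 and wild-type mycelium became 65 with upper-quartile factors, 73 with CPM above 5 in 2 libraries, 445 with DESeq2, 47 with limma-voom, 75 with a 2-fold minimum and 61 with plain library totals. Leaving out a nox1 replicate gave 152 to 1344. Of the 118 genes, 114 were kept without nox1 mycelium replicate 1, 115 without nox1 mycelium replicate 2, 105 without protoperithecia replicate 1 and 102 without protoperithecia replicate 2. The 3200 genes changed between protoperithecia and mycelium became 1879 with a 2-fold minimum and 833 to 5906 without a replicate, where a lone library was assumed to vary like the others. Without a mycelium replicate the spread came from the protoperithecia pair, which differ less. Upper-quartile factors and plain totals moved the median of all genes in the mycelium comparison by 0.18 and 0.23 on the log2 scale. The cause of the changes in the number of calls was not tested. A replicate block gave 3610 genes, 3073 of them in common with the 3200. The deviations of same-numbered libraries correlated at 0.057 across genes. That value rests on 1 pair of libraries per tissue, so it cannot exclude pairing. The 4 overlaps with the authors' calls kept their direction and stayed past the threshold in every setting run, with ratios of 3.61 to 13, 3.26 to 9.17, 2.74 to 6.42 and 2.01 to 12 in the order reported. The 8 named genes kept their sign in all settings run, with the call kept in 101 fits and lost in 6. The tests of gene lists and the nox1 transcript level were not run. In simulations at this depth and replication, 26% and 15% of changes of log2 size 2 were recovered for protoperithecia and for mycelium.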

Other observations

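The test of the flanking genes, the count of lower genes without nox1 mycelium replicate 1 and both tests on 8-fold changes were set out ahead of their results, and the other tests were chosen after the result was seen. No gene with 50 or more counts in wild-type mycelium had 0 counts in all 4 nox1 libraries (0 genes). Among the 9166 genes with at least 1 CPM in wild-type mycelium, 13 were below 2% of the wild-type level in every nox1 library. Near 1 CPM, 2% lies below the floors of the nox1 libraries (0.0539 to 0.0783 CPM), so few weakly expressed genes could pass. Reads over otherwise silent genes in nox1 mycelium replicate 1, described below, can also keep genes out of both counts. Neither count therefore measures how many genes lose expression in nox1.

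Genes reduced in nox1 mycelium included adjacent pairs more often than permuted calls. On assembly ASM3387043v1 they formed 4 adjacent pairs, against a mean of 1.2 in 10000 permutations of the calls (ratio 3.33, one-sided permutation p = 0.033, 0.044 after Benjamini-Hochberg adjustment over 4 tests). Adjacent here means consecutive among the tested genes with a matched locus tag, so other genes may lie between the members of a pair. The lower and higher genes of protoperithecia formed 276 and 278 pairs against 248 and 251 (ratio 1.11 in both, permutation p = 0.02 and 0.024, 0.044 after adjustment), and the raised genes of nox1 mycelium formed 0 pairs. Neighbouring genes may change together in the mutant, a hypothesis that rests on few pairs in mycelium. On this assembly all 4, 276 and 278 pairs were free of overlap between their genes. Other ways for adjacent genes to share reads were not tested, and the annotation used for counting is not given.

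Nox1 mycelium replicate 1 had reads over genes that were silent elsewhere. The 174 genes longer than 300 bases and below 0.3 RPKM in the other 4 libraries had a median of 3.86 RPKM there (quartiles 2.28 and 5.77). The same rule gave 3 genes for each of the other libraries. That count decides nothing about them. The rule then required under 0.3 RPKM in nox1 mycelium replicate 1, whose 1st percentile was 1.59 RPKM. Reads running over from flanking genes could not be separated from other sources: the rho with the higher flanking gene was 0.087 (permutation p = 0.257), too close to the limit of 0.2 set for it. Even background such as genomic DNA stays open as well, since the interquartile ratio of 2.53 exceeded the 1.14 of counting error but uneven mapping can widen it. Counts over the 174 genes rose with gene length (rho 0.659), as even background would give. Over 1150 genes silent in the protoperithecia the rho was 0.705 in this library and 0.599 in the wild type, so length does not separate the sources. No biological explanation was tested. These extra reads are called background below, with their source left open.

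The genes reduced in nox1 mycelium were weighed against chance values of the single wild-type library. Chance values that are independent between genes do not carry over to other libraries. The overlap with the pro1 calls was 8.28 times chance (4.61 and 3.26 without nox1 mycelium replicate 1 or 2). That expectation was not matched on the wild-type level, so an effect of wild-type abundance was not excluded. Nor could the overlap exclude a deviation of that culture shared by many genes. The background in nox1 mycelium replicate 1 adds reads and would raise a gene there, so the fit without that replicate (747 lower genes, 597 higher genes, 114 of the 118 called genes still called) decides nothing about it. The larger counts came with the smaller spread of the remaining replicates. A difference in the developmental stage of the wild-type culture stays open, and no biological explanation was tested.

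Among changes of 8-fold or more in protoperithecia, 80.9% were decreases. Without nox1 mycelium replicate 1 the share was 73.7%, so its background is not the whole cause. In the genes above the 75th percentile of length it was 77.1% (95% interval 72.1 to 81.5), which argues against a loss of short transcripts on amplification as the whole cause of the 8-fold decreases, while the rho of 0.237 between length and log2 fold change leaves a part of it open. Other effects of amplification cannot be told apart from tissue, since each protoperithecia library was amplified and no mycelium library was. The share was 94.5% with upper-quartile factors, 64.9% with limma-voom, and 71.5% and 71.4% without protoperithecia replicate 1 or 2.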
